A study of Homo sapiens with 6 samples.

How the data were processed

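Total RNA of TMZ-resistant and TMZ-sensitive U87 cells was extracted with Trizol, labelled with Cy3 by the Agilent Quick Amp kit and hybridised to 6 one-colour Agilent arrays, 3 per line, per the labels' protocols. Groups and replicate numbers were taken from the sample titles. The deposited scanner output gives an intensity per spot for 61184 spots per array. Per the file headers, Agilent Feature Extraction 11.0.1.1 made these values from a 20-bit scan, subtracting background and correcting spatial trends within each array, with no scaling between arrays. Flags per spot, a 0 or 1 for well above background, saturated or outlier, are the authors' deposited Feature Extraction output as well, per the file headers. All 6 arrays came from 1 slide and 1 scan. The resistant arrays filled row 2 of the slide and the sensitive arrays row 1, so slide row and line cannot be told apart.

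The authors also deposited a matrix of log2 values for 49575 probes, with no account of its making in the sources used here. Set against the scanner values, 99.8% of its values lay within 0.05 of quantile-normalized log2 processed signals, so its scale and direction are known, and no centring of probes was seen. Its column medians were 8.14, 8.14, 8.14, 8.14, 8.15 and 8.14. All of its probes were well above background on at least 3 arrays, as were 50980 of the array probes in all. It was used as an alternative source of values and held none of the 20 named probes.

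The processed signal was put on the log2 scale and each array's 75th percentile was subtracted. Control spots and the probes named Negative were left out, as were 213 probe values carrying an outlier mark. No array probe was saturated. Spots of a probe were averaged on the log2 scale. Probes well above background on at least 3 of the 6 arrays, with a value in both lines, were tested, giving 50995 probes, and 5 probes whose values were all marked as outliers in a line were dropped. The lines were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. A log2 fold change is resistant minus sensitive. The same steps were tested on simulated data for 50995 probes with the spread of the real arrays. Of 100 probes changed 2-fold, 27% were recovered, and of 100 changed 4-fold, 86%, with 7 false calls. Only these 200 probes were changed, whereas 29.3% of the tested probes were called in the real data. The adjustment is stricter where few probes change, so these shares do not give the power of the real comparison. Figures were drawn with matplotlib 3.10.9.

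The processed files pair no gene name with the 58945 probes that have a single spot. The 20 named genes have probes with 10 spots each that carry RefSeq accessions, all of which matched the RefSeq gene table of assembly GRCh38.p14, used for names only. No coordinates are given because the array design is on hg19, per the file headers. The naming rule fixed before the data were examined took the genes of DNA repair, the coding and non-coding genes with the widest changes among those that passed without overlap of the lines, and members of 37 fixed gene lists. Only its part on coding genes could be applied, to the 20 named genes, and genes that did not pass are named beside them for completeness. All 20 are in the counts, but 2 of them are not reported here singly. The split into coding and non-coding genes, the gene list tests and the comparison of antisense genes with their hosts could not be run for want of names. The further GAPDH and PGK1 probes belong to the control set of the array and were compared with a two-sided exact permutation test.

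The test, filter, scaling and most alternatives were chosen before the data were examined. The alternatives were normexp background correction with an offset of 50, quantile and median scaling, no filter and a filter of all 6 arrays, the authors' deposited values, an intensity trend with a robust prior, the replicate number as a block, a threshold of 0.01 and leaving out each array in turn. Normexp was run on the median spot signal and the median local background, where the plan had named the mean spot signal. Keeping the outlier spots and scaling to GAPDH or ACTB were added later.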

Results

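RNA was profiled in U87 cells, a human glioblastoma line, and in a derivative of U87 that withstands temozolomide (TMZ), a DNA-alkylating drug used against glioblastoma. The resistant cells had been raised from the parental sensitive cells by exposure to stepwise higher doses of the drug. Each line was measured on 3 arrays, giving 6 one-colour arrays that carry probes for messenger RNAs and long non-coding RNAs. Nothing in the labels says that the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. The share of array probes well above background was 80.1%, 86.9% and 84.8% on the resistant arrays and 84.0%, 86.5% and 86.8% on the sensitive arrays. The 75th percentile of the probe signals lay between 686 and 808 in all 6. The number of arrays limits the precision of every value given here.

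The comparison asks how the messenger RNA and long non-coding RNA profiles of the resistant line differ from those of the sensitive line. Of the 20 protein-coding genes whose probes could be named, ODC1, which encodes ornithine decarboxylase, the rate-limiting enzyme of polyamine synthesis, differed most. ODC1 was 12.6-fold higher in the resistant cells (95% confidence interval 7.20 to 21.9, limma adjusted p = 0.000268), and higher in all 3 resistant arrays than in any sensitive array. Its log2 signal relative to the array's 75th percentile was 6.04 ± 0.14 (SD, n = 3) in resistant and 2.39 ± 0.73 (SD, n = 3) in sensitive cells. The median of its 10 spots was 47050 to 56850 on the resistant arrays, against 3115, 6410 and 3330 on sensitive replicates 1, 2 and 3. By size of change, ODC1 was beyond 99.0% of all tested probes and beyond 99.1% of the 341 probes of similar brightness.

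The other genes that passed the test changed by less than 2-fold. ARHGDIA rose 1.73-fold (log2 change 0.79, SE 0.16, limma adjusted p = 0.00907). DYNLL1, a light chain of the dynein motor, rose 1.65-fold (log2 change 0.72, SE 0.17, limma adjusted p = 0.0190). PGK1, a glycolytic enzyme, fell by 0.82 on the log2 scale (SE 0.17, limma adjusted p = 0.0106). COX4I1, a subunit of mitochondrial cytochrome c oxidase, fell by 0.65 (SE 0.17, limma adjusted p = 0.0257), and the glycolytic enzyme GAPDH fell by 0.58 (SE 0.13, limma adjusted p = 0.0136). For each of these genes the 3 resistant arrays lay on one side of the 3 sensitive arrays. Of the 20 genes 7 passed in all, and the same number passed when adjusted over the list alone.

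**Figure D1:**
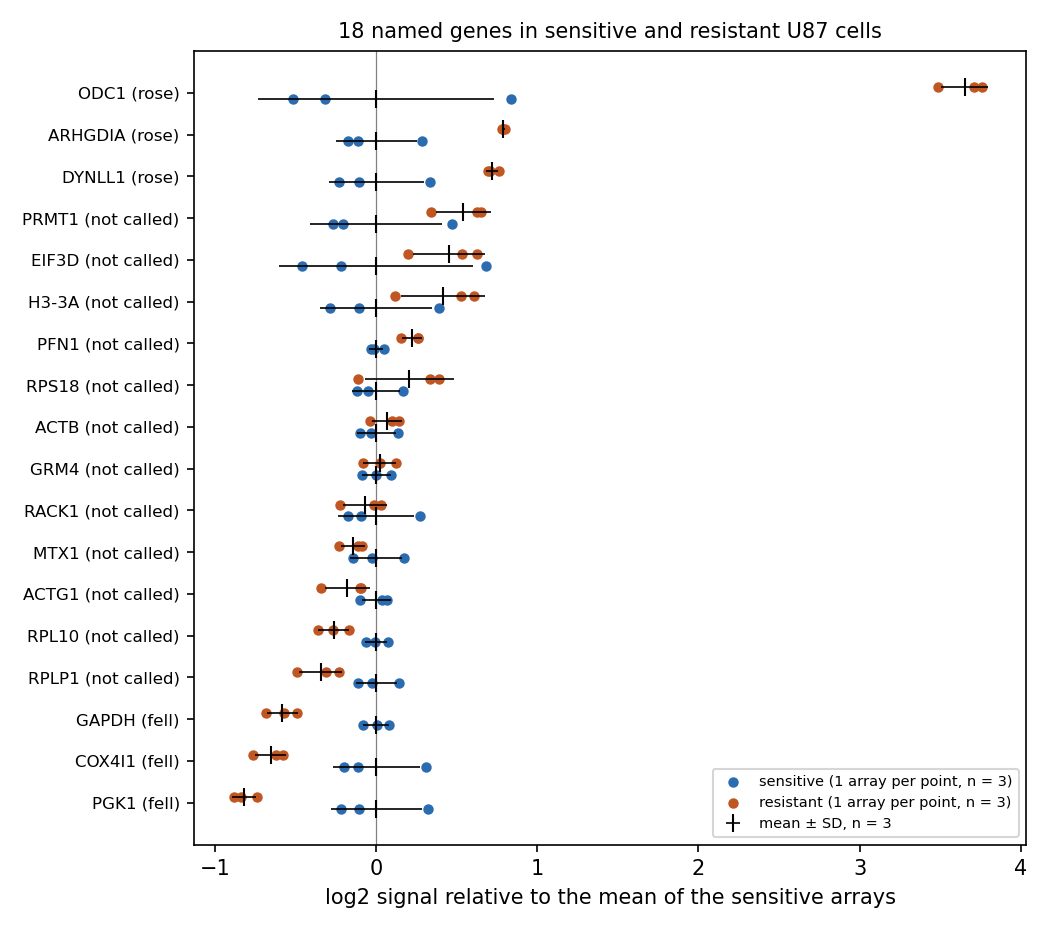
Log2 signal of 18 named genes on each array, as the difference from the mean of the sensitive arrays (horizontal axis), 1 point per array (n = 3 per line), with the mean ± SD of each line in black. The resistant points of ODC1 lie near a log2 change of 3.65, and those of PGK1, COX4I1 and GAPDH lie left of all sensitive points.

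The remaining 13 named genes did not pass. Their log2 differences (resistant minus sensitive) ran from -0.35 for the ribosomal protein gene RPLP1 (limma adjusted p = 0.113) to 0.54 for the arginine methyltransferase gene PRMT1 (limma adjusted p = 0.117). The cytoskeletal gene ACTB differed by 0.07 (SE 0.13), with a 95% interval of the fold of 0.842 to 1.31. For ACTG1 the log2 difference was -0.18, for PFN1 0.22, for RPS18 0.21, for RPL10 -0.26 and for RACK1 -0.07. The RPL10 probe was far dimmer, with signals of 402 to 538 over the arrays against 210361 to 301096 for RPS18. On sensitive replicate 2, several of the genes that did not pass were close to their resistant level. Without that array PRMT1 (0.78), EIF3D (0.79) and H3-3A (0.61) were among those that also passed, with limma adjusted p of 0.00820, 0.0167 and 0.0456.

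GAPDH and PGK1 were each measured with further probes near the 3′ and the 5′ end of the transcript. The GAPDH probes differed by -0.55 (3′) and -0.83 (5′) and the PGK1 probes by -0.80 (3′) and -1.07 (5′) on the log2 scale, resistant minus sensitive. All 3 resistant arrays lay below all 3 sensitive arrays for each of the 4 probes. The two-sided exact permutation p was 0.1 for each, the smallest that 3 arrays against 3 allow. Of the gene lists fixed before the data were examined, only 3 of 37 had any named member, and none had the 3 members a list test needed. These were GAPDH and PGK1 (hypoxia and glycolysis), COX4I1 (oxidative phosphorylation) and RPLP1 (ribosomal proteins), so nothing is said here of those groups as a whole.

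ODC1, ARHGDIA and PGK1 passed in each of 14 alternative settings with a scaling to the whole array and a threshold of 0.05, whereas DYNLL1 passed in 9, GAPDH in 10 and COX4I1 in 8. Over these settings the limma adjusted p ranged from 0.00211 to 0.0719 for DYNLL1, from 0.00523 to 0.333 for GAPDH and from 0.0128 to 0.0941 for COX4I1. DYNLL1 was lost without any array other than sensitive replicate 2 (0.0554 to 0.0719). GAPDH was lost without resistant replicate 3 (0.0641), sensitive replicate 1 (0.0531) or sensitive replicate 3 (0.0537), and with quantile normalization (log2 change -0.22, 0.333). COX4I1 was lost in 6 settings, among them without any 1 resistant array (0.0690, 0.0812 and 0.0632 for replicates 1, 2 and 3), without sensitive replicate 3 (0.0559) and with quantile normalization (log2 change -0.44, 0.0941).

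Across the whole array, 14917 of 50995 tested probes (29.3%) differed between the lines at a limma adjusted p under 0.05. Of these, 8017 (53.7%) were higher and 6900 lower in the resistant cells. A change of at least 2-fold was found for 7878 probes, 4521 of them higher and 3357 lower. Among the preset alternatives at a threshold of 0.05, normexp background correction gave the fewest such probes (5382, with 3071 higher and 2311 lower). Leaving out sensitive replicate 2 gave the most (8924). At least 4-fold changes were seen for 1308 higher and 1115 lower probes. At 8-fold or more the larger number was on the lower side, with 453 higher and 501 lower probes. The same held at 16-fold or more, with 165 higher and 234 lower probes. With probes not well above background in a line counted at their lower bound, the numbers at 16-fold or more were 100 higher and 184 lower. The median absolute log2 change was 0.35 over all tested probes and 1.04 over those that passed. In 45.1% of tested probes the 3 resistant and the 3 sensitive arrays did not overlap, against 10% by chance. Each line filled its own slide row, so a position effect may contribute to this share and to the calls. Scaled to GAPDH in place of the 75th percentile, a choice made after seeing the data, 25914 probes were higher and 2677 lower, and PGK1 (-0.24) and COX4I1 (-0.07) no longer passed.

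**Figure D2:**
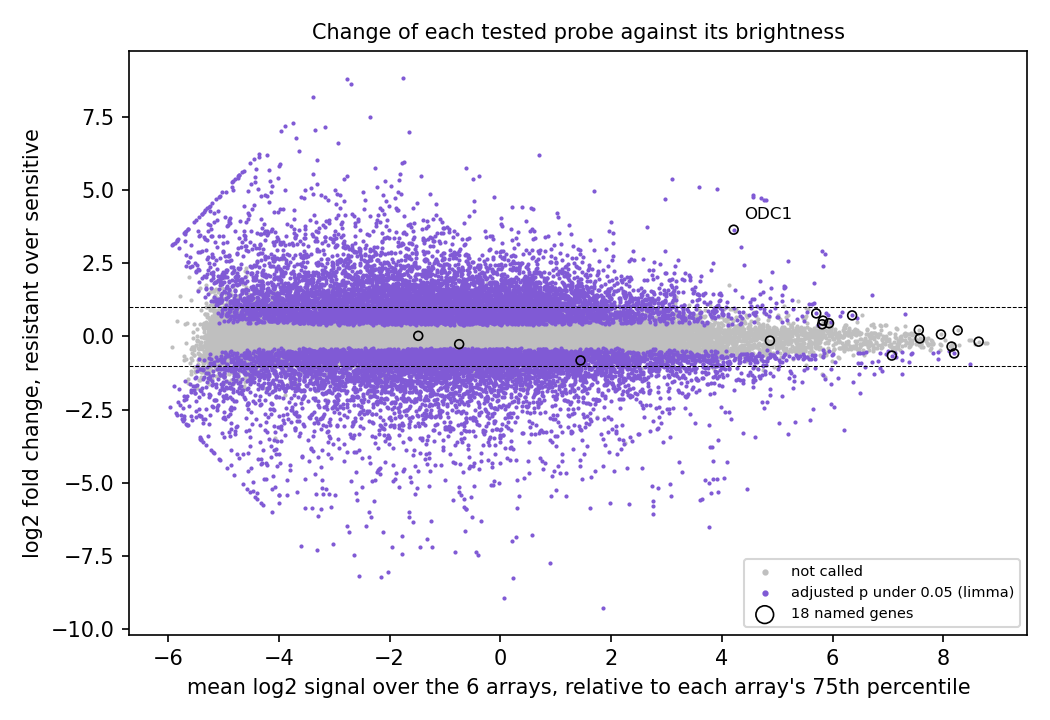
Log2 fold change of each tested probe (resistant over sensitive, vertical axis) against its mean log2 signal over the 6 arrays (horizontal axis), with probes past an adjusted p of 0.05 in purple, the others in grey, 18 named genes as open circles and dashed lines at 2-fold. Of the 50995 probes, 4521 lie above the upper line and passed, 3357 lie below the lower line and passed, and ODC1 stands apart from the other named genes.

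The changes were spread over the range of brightness. When the tested probes were divided by brightness into 4 equal groups, 2817, 3751, 4275 and 4074 probes passed from the dimmest to the brightest group. With at least a 2-fold change, 14.0%, 15.3%, 16.8% and 15.7% passed. Between arrays of the same line, Pearson's r across probes, which are not independent replicates, was 0.984 to 0.986 in resistant and 0.975 to 0.989 in sensitive cells. Between the lines it was 0.911 to 0.919. The SD of the log2 differences was 0.37 to 0.56 for 2 arrays of a line and 0.97 to 1.05 for arrays of different lines.

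Some probes were flagged well above background in only 1 of the lines. The flag alone does not show that a transcript was present in a line or absent from it. Of 60 probes named Negative, 26 carried it on all 6 arrays. A total of 304 probes were well above background on all 3 resistant arrays and on no sensitive array, of which 301 passed the test. Another 429 showed the opposite, of which 340 passed. Where a line was not well above background on any array, only a lower bound of the fold is given, set against the lowest signal among probes well above background on each array, or the probe's own signal if higher. Probes whose bound did not lie in the direction of the change were left out of the medians. Over the rest, the median bound was 3.55-fold for the probes seen in resistant cells and 1.72-fold for those seen in sensitive cells. At least 4-fold was reached by 138 and 94 probes. The processed files used here do not pair these probes with genes. The widest measured changes included ASHGA5P003924, at least 229-fold higher (limma adjusted p = 2.6e-06), and ASHGA5P034538, at least 111-fold higher in resistant cells (limma adjusted p = 4.4e-06). ASHGA5P053191 was well above background on all 6 arrays and fell by 9.29 on the log2 scale (SE 0.24, limma adjusted p = 2.6e-06). ASHGA5P017141 was well above background on 2 of the 3 resistant arrays and fell by 8.94 (SE 0.32, limma adjusted p = 5.2e-06).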

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

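The comparison of control probes at 2-fold, the 5′ and 3′ signals on sensitive replicate 2, and the signal of resistant-only probes there were tests chosen only after the result was seen. No group has the 4 samples that a search for outlying samples needs.

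A signal appeared in data that the comparison of the lines does not use. Of 60 probes named Negative on the array, 26 were well above background on all 6 arrays, while none of 308 dark control spots was. The brightest had a mean signal of 1256 over the arrays (1076 to 1438), against 23.0 for the median Negative probe, and 2 of the 60 differed between the lines, 0 of them by 2-fold.

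The first pattern is the large number of probes that differ between the lines. The choice among scalings to the whole array is argued against as its cause. Median scaling called 15103 probes, 14540 of them among the 14917, and quantile normalization 15399, with 14334 among the 14917. Such scalings align the bulk of the probes, so they cannot show a shift of the whole array. Scaled to GAPDH, 25914 probes were called higher and 2677 lower, and scaled to ACTB, 6867 higher and 6883 lower. The balance of directions therefore depends on the reference. A difference in hybridisation between the slide rows may account for part of the calls, as slide row and line cannot be told apart. Of 113 control probes counted on the array, 49 without a human target entered this comparison. Of these 49, 8 were called (16.3%, against 22.1% of array probes of matched brightness). The SD of their log2 differences was 0.551 of that at the matched probes (95% bootstrap interval 0.425 to 0.674). This lay above the preset limit of 0.5, under which a row difference would have been argued against. Changes of 2-fold or more may be less open to a row difference, as 0 of the 49 control probes reached 2-fold against 90 of 980 matched probes (Fisher's exact p = 0.0175). With only 49 control probes, a row difference behind part of these changes is not excluded. Of the 10 splits of the 6 arrays into 3 and 3, 1 gave as many calls, the real one. It had 14917 calls against at most 0 in the others, and likewise 7878 against 0 at 2-fold. A mixed split puts any difference between lines or slide rows into the spread within its groups. Few calls were thus bound to follow there, and the contrast with 0 says little. The 10 splits are also too few for a share under 0.05, and the biological difference between the lines stays open.

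The second pattern is that sensitive replicate 2 lies apart from the other 2 sensitive arrays, with 9452 probes at least 1.5-fold away from their mean, 82.4% of them towards the resistant mean (53.9% and 57.2% for sensitive replicates 1 and 3). The share towards the other line was 64.8%, 65.4% and 79.6% for resistant replicates 1, 2 and 3, of 2222, 2817 and 2275 probes. A high share is thus not particular to sensitive replicate 2, though its number of probes is the largest. RNA of resistant cells in that sensitive sample, as the sole cause, is argued against by the following shares of the resistant signal. A small amount of such RNA is not excluded. The 82.4% towards the resistant mean did not argue against such RNA, and the shares of the resistant signal were examined only after that value was seen. The median share was 0.980% over 107 bright probes, taken from a set of 425 that is larger than the 304 probes described above. For ODC1 the share was 8.73%. The 4131 probes that fell at least 1.5-fold on sensitive replicate 2 would need a share of 33.3%. A scale or brightness trend is also argued against, since the spread of its differences stayed 1.46 times that between the other arrays after quantile normalization. Labelling that reached further towards transcript 5′ ends stays undecided: the 5′ minus 3′ log2 signal lay 0.51 (GAPDH) and 0.57 (PGK1) above the other sensitive arrays, but resistant replicate 2 departed from its own group by -0.61 and -0.21 with only 2817 probes moved by 1.5-fold. A difference in the state of the culture was not tested.

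The third pattern is the rise of ODC1. Local spot defects are argued against: the dimmest of the resistant spots, after scaling, was 5.80 times the brightest sensitive spot, over 10 spots per array. Binding of another transcript to the probe stays open, since 0 further probes could be named as ODC1. A higher ODC1 transcript level in the resistant line is therefore one of the open explanations, and a further probe or a separate assay would be needed.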

How the results depend on the processing

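The scalings to GAPDH and ACTB and the kept outlier spots were tests chosen only after the result was seen. Under the alternatives chosen beforehand the number of probes called stayed within 1.5 times 14917, except at a threshold of 0.01, where a stricter limit left 8879 (5100 higher, 3779 lower). Of the 14917 probes, 14540 were also called with median scaling, 14334 with quantile normalization, 13519 with normexp and 13275 with no filter, and 14014 of the 14546 that the authors' values hold. Scaling to GAPDH, which fell itself, moved the median log2 change of all probes from -0.03 to 0.55; it gave 28591 calls, 25914 higher and 2677 lower, 12380 of at least 2-fold (10756 higher, 1624 lower) and 11 named genes, while scaling to ACTB gave 13750 calls. Leaving out 1 array gave 10650 (without sensitive replicate 3, 10477 of them among the 14917) to 19865 calls (without sensitive replicate 2, 14275 among the 14917) and 4 to 11 named genes in place of 7: 4 without resistant replicate 3 or sensitive replicate 3, and 11 without sensitive replicate 2, and apart from the smaller number of arrays the cause was not tested. Among single named genes, 286 values stayed on their side of the threshold, 14 newly passed and 18 no longer passed, and none that had passed changed direction; quantile normalization added RPS18 (0.48) and PFN1 (0.46). Nothing in the labels says whether the replicate numbers pair the arrays. Deviations of same-numbered arrays correlated at 0.240, 0.0571 and 0.203, and each array matched its own number best. That is a hint of pairing from the data only, and same-numbered arrays share a slide column. With the number as a block, 14414 probes were called, 13281 of them among the 14917, and 6 named genes, as COX4I1 no longer passed (limma adjusted p = 0.0581, 0.0128 to 0.0941 over 14 settings). Leaving out saturated probes removed none, blocks for slide and scan were not run with 1 of each, and alternatives for gene lists, non-coding genes, antisense pairs and the choice of probe per gene were not run for want of names. Dim signals limit the rest: 5142 probes were well above background on no array.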

Other observations

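The tests on GAPDH and ACTB as references were chosen only after the result was seen. GAPDH and ACTB, genes often used as references, moved apart between the lines: scaled to ACTB, GAPDH had a log2 change of -0.65 (limma adjusted p = 0.0305), against -0.58 with the whole array as reference. ACTB itself differed by 0.07 (SE 0.13) relative to the whole array, and its log2 difference ran from 0.02 to 0.36 over 14 settings. Values relative to GAPDH place the median probe 0.55 higher in the resistant line, and those relative to ACTB place it at -0.10.

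Probes well above background on all arrays of 1 line and on none of the other numbered 733, with the larger part, 429, on the sensitive side. Among those with a lower bound of at least 4-fold, the larger part was on the resistant side, with 138 probes against 94. The other splits of the 6 arrays into 3 and 3 gave at most 238 probes flagged in 1 group only. That split set resistant replicates 1 and 3 and sensitive replicate 1 against the rest. These 3 arrays had the lowest shares of probes well above background (80.1%, 84.8% and 84.0%, against 86.5% to 86.9%). Such numbers may thus also reflect detection on single arrays. Probes flagged in 1 line only cannot count in a mixed split, so 238 does not measure what chance would give. Among the probes past 2-fold, the share higher in resistant cells was 59.5%, 60.6%, 58.7% and 51.0% from the dimmest to the brightest of 4 equal groups of probes. The share was not tested for a trend.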
